A study of Arabidopsis thaliana with 9 samples.

How the data were processed

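Root RNA of Arabidopsis thaliana was measured on 9 Affymetrix arrays, 3 each of the wild type Col-0 and of the mutant lines myb36-1 and myb36-2. Per the labels' protocols, plants grew for 2 weeks on agar plates of MGRL medium, a defined nutrient medium, with sucrose, and total RNA of the roots was labelled with biotin. The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes; RMA corrects background, equalises array distributions and summarises the probes of each probe set. Its version, and whether all 9 arrays were normalised together, are not given in the sources used here. The median of all deposited log2 values was 4.61 ± 0.02 (SD, n = 3) in Col-0, 4.60 ± 0.01 in myb36-1 and 4.86 ± 0.01 in myb36-2. Since RMA equalises array distributions, this gap argues against a joint normalisation of all 9 arrays. The scale of the myb36-2 arrays relative to the others stays unknown. Pearson correlations across probe sets were 0.990 to 0.994 within lines and 0.979 to 0.992 between lines. The small number of arrays limits the precision. No label says that the arrays of a line came from separate cultures, so the p-values measure the spread between these arrays only, which may be technical.

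The value table holds 38408 probe sets, of which 17481 are paired with a gene in the platform annotation: 16722 with 1 gene and 759 with several. A gene was named only from a probe set with 1 gene, which gave 16548 genes; 16715 of those probe sets matched a gene of the reference table (assembly TAIR10.1), used for names and gene order only. The first 7083 probe sets in identifier order, none of them paired with a gene and with 1991 distinct value patterns, were left out as control-like, although no source names them as controls. The remaining 31325 were tested, 13844 of them unnamed here. The annotation names 17.1% of the protein-coding reference genes that have a symbol and 86.3% of those known by locus only, so many well-known genes are not analysed here. No probe set is named for MYB36, and the line labels were therefore not checked against its transcript.

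Each probe set was fitted in limma 3.58.1 (R 4.3.3) with 1 mean per line over all 9 arrays, moderated by empirical Bayes without trend, and 4 contrasts were tested two-sided: each mutant against Col-0, the mean of both mutants against Col-0, and myb36-1 against myb36-2. Calls had a Benjamini-Hochberg adjusted p under 0.05. A probe set counted as changed in both mutants when it was called in each with the same sign. Log2 changes are given with the standard error of the fit. Because scaling moved the share of rises by more than 10 percentage points, counts are also given after quantile normalisation of the deposited values over all 9 arrays, called the common scale; the median log2 change over all tested probe sets was 0.16 in myb36-2 and -0.01 in myb36-1 as deposited, and -0.01 in myb36-2 on the common scale.

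Of 21 gene lists with 309 genes, 44 genes were measured; 5 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, on the brightest probe set of each gene. For 8 lists no member was named. Genes to be named were fixed by rule before the data were examined: all measured Casparian strip genes, the 12 largest rises and 12 largest falls shared by both mutants, the 5 largest in each direction per mutant, the 6 highest and 6 lowest differences between mutants, and up to 4 members of each other list. Other named genes were chosen after their values were seen, and this is said where they appear. Calls were also counted in windows of 100 measured genes in locus order, with Bonferroni adjustment over windows.

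On simulated data with 200 changed among 31325 probe sets, the myb36-1 contrast recovered 87 of 100 changed by 1 log2 unit and 99 of 100 changed by 2 units, with 11 false calls. The calls in both mutants recovered 85 and 99 of 100 with 2 false calls. The simulated noise was normal and independent between probe sets, with the same changes in both mutants and no shift of scale. Its false calls may therefore understate those in the real data, above all in myb36-2. Alternatives covered scaling, filters on dim probe sets, moderation, array weights, arrays in the fit, the replicate number as a block, 1 probe set per gene, stricter thresholds, window width and the omission of each array. Added after the data were examined were the inclusion of all deposited probe sets, the counting of identical ones once, the window test on the common scale and a list of class III peroxidases. The test of the scale of the myb36-2 arrays was also replaced after earlier forms had been seen: the first used the share of rises after quantile normalisation, which that step itself sets, and the second did not match probe sets by level. The test of whether myb36-2 calls move the same way in myb36-1 was revised after earlier forms of it had been seen: the first chose its probe sets with all Col-0 arrays, and the second set no interval on the share. The rule for reading the test of the peroxidase family was also revised after its result had been seen.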

Results

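Transcript levels in 2-week-old roots were compared between wild-type Arabidopsis (Col-0) and 2 lines, myb36-1 and myb36-2, carrying mutations in MYB36, a transcription factor known for directing formation of the Casparian strip, the lignin barrier of the root endodermis. Each line was represented by 3 arrays. The arrays of myb36-2 had a median of 4.86 on the log2 scale, against 4.61 in Col-0 and 4.60 in myb36-1.

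**Figure D1:**
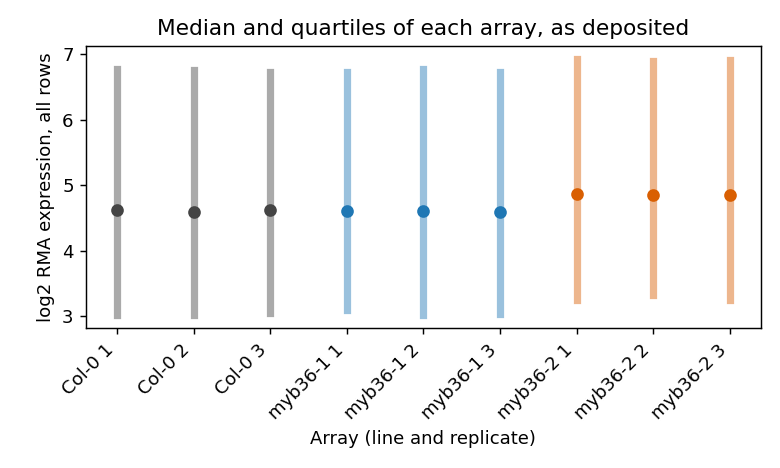
Median (point) and quartiles (bar) of all deposited log2 RMA values on the y axis for each array on the x axis, coloured by line. The 3 myb36-2 medians lie between 4.85 and 4.87, above the 6 other arrays.

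The first question was which transcripts changed in both mutants. Among the named genes called in both, DIR9 and DIR24, members of the dirigent protein family, fell the most in the mean of both mutants. DIR9 changed by -3.07 ± 0.12 (SE, n = 3 arrays per line) in myb36-1 and -3.84 ± 0.12 in myb36-2, and DIR24 by -2.20 ± 0.22 and -5.31 ± 0.22. AT1G71740 changed by -2.65 ± 0.19 and -3.84 ± 0.19, and AT2G40113 by -3.21 ± 0.16 and -3.04 ± 0.16. The peroxidase gene PRX52 rose by 2.85 ± 0.16 in myb36-1 and 2.57 ± 0.16 in myb36-2, and AT5G52390 by 2.18 ± 0.22 and 3.03 ± 0.22. Adjusted p in limma was 0.0029 or lower for each of these 6 genes in both mutants.

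Further genes that fell in both mutants were AT1G30750 (-2.20 and -2.83 in myb36-1 and myb36-2), AT5G52790 (-2.38 and -2.20), AT1G43020 (-1.85 and -1.90), AT5G65530 (-1.65 and -1.72), AT4G02090 (-1.40 and -1.52) and AT5G43540 (-1.30 and -1.46). AT3G48346 changed by -1.33 and -1.41, and AT5G42655 by -1.34 and -1.33. Genes that rose in both were AT1G65500 (2.34 and 2.45), the peroxidase gene AT1G49570 (2.05 and 2.50), AT1G30760 (1.66 and 1.73) and PER71 (1.28 and 1.70). AT1G51920 and AT4G00910 also rose in both, by 1.81 and 1.69 in the mean of both mutants. AT5G19240 rose by 0.98 and 2.00, AT4G12490 by 1.44 and 1.51, AT5G09290 by 1.02 and 1.64, and AT5G36925 by 0.83 and 1.64. AT5G09290 and AT5G36925 lay near the threshold in myb36-1, with adjusted p in limma of 0.050 and 0.049, and the call of AT5G36925 there was lost on the common scale. The myb36-1 calls of AT5G19240, AT4G12490, AT5G09290 and AT5G36925 were each lost when certain single arrays were left out.

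**Figure D2:**
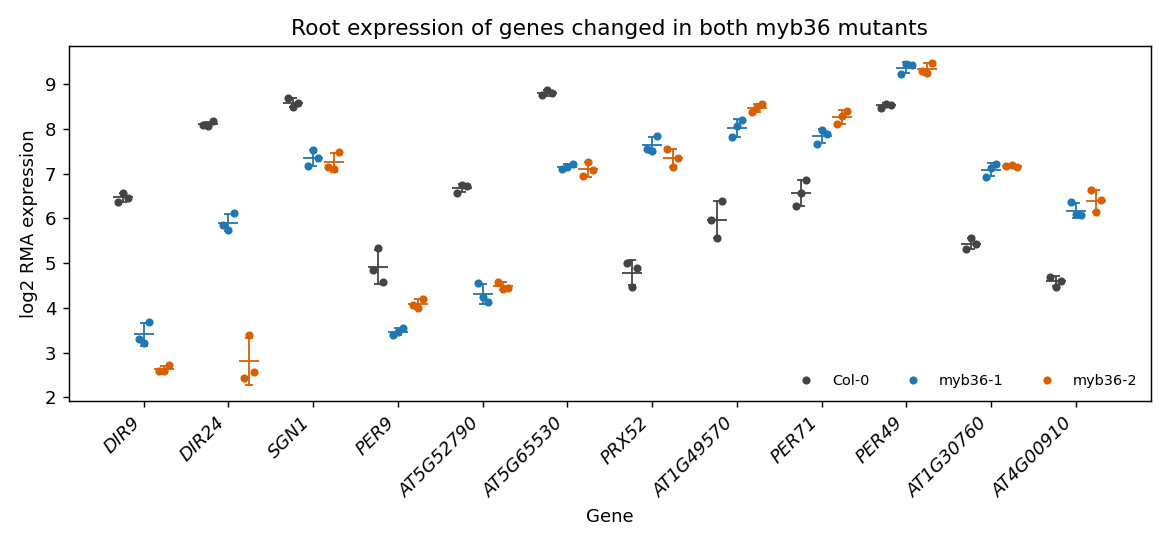
Deposited log2 RMA expression (y axis) of 12 genes (x axis) on each array, coloured by line; points are arrays, the horizontal mark is the mean and the bar the SD (n = 3). DIR24 had a mean of 8.11 in Col-0, 5.91 in myb36-1 and 2.80 in myb36-2, while PRX52 had 4.79, 7.64 and 7.36.

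In all, 131 probe sets were called in both mutants with the same sign, 70 higher and 61 lower, and 69 of them were named genes, 40 higher and 29 lower. The other 30 higher and 32 lower probe sets were unnamed or not the brightest of their gene, and were not ranked. On the common scale 130 probe sets were called in both, of which 117 were among the 131. Independent lists of these sizes would share 13.7 higher and 1.70 lower probe sets, and simulated unchanged groups set against the same Col-0 arrays shared 0.01 on average, where 132 were observed in either sign. Across probe sets, which are not independent, log2 changes in the mutants correlated with r = 0.55 against 0.50 in that simulation, and their covariance was 0.0452 against 0.0115. As deposited 62.7% of probe sets had the same sign in both mutants, and 67.4% on the common scale, against 66.7% simulated. The simulation holds no effects and the independent lists share no controls, and the 3 Col-0 arrays do not give 2 to each part of a split, so part of the excess of shared calls may come from the shared controls. Leaving out any single Col-0 or myb36-1 array brought the count to between 69 and 82.

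**Figure D3:**
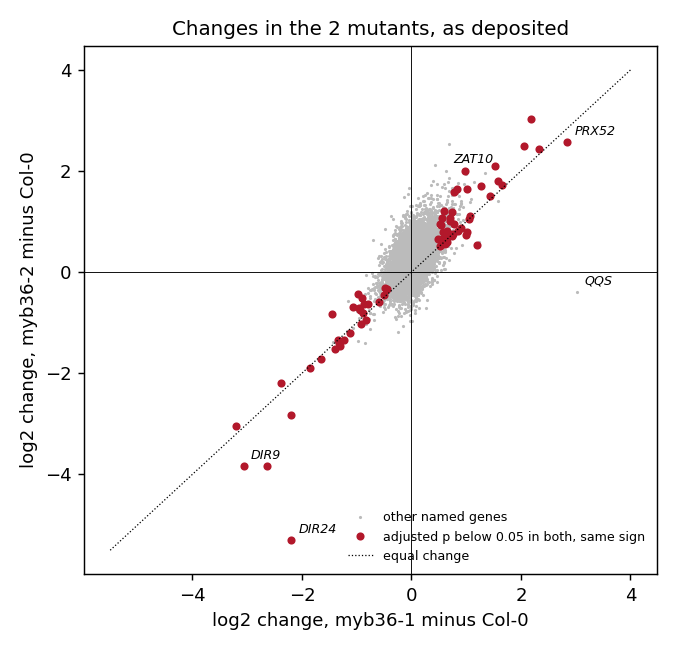
Log2 change of each named gene in myb36-1 (x axis) and myb36-2 (y axis) against Col-0, as deposited; red points passed an adjusted p of 0.05 in both mutants with the same sign, grey points are all other named genes, and the dotted line marks equal change. DIR24 lies at -2.20 and -5.31, and QQS at 3.02 and -0.40.

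Casparian strip genes were examined as a group because of the role known for MYB36; the list draws on published work that includes these mutants and is not independent evidence of direction. Of 23 listed genes 11 were measured, and the CASP genes and ESB1 were not among them. Of the 11, 4 fell and 0 rose in myb36-1, and 6 fell and 1 rose in myb36-2. DIR9, DIR24, SGN1 (a receptor-like kinase of barrier surveillance) and the peroxidase gene PER9 fell in both, SGN1 with changes of -1.24 and -1.34 and PER9 with -1.45 and -0.83. DIR18 changed by -1.43 (adjusted p = 0.052 in limma) in myb36-1 and fell by 1.38 in myb36-2. PER72 was -0.35 in myb36-1 without passing and fell by 0.40 in myb36-2, whereas PER39 was 0.29 without passing and rose by 0.49. LOTR1, whose product positions the strip, changed by -0.27 in the mean of both mutants (adjusted p = 0.047). GSO1, the receptor of the CIF peptides, and the peptide genes CIF1 and CIF2 did not pass, with mean changes of -0.16, -0.15 and 0.06.

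In the mean of both mutants, 6 of these 11 genes fell and 1 rose, and 8 passed when adjusted over the list alone. The list shifted down in camera (adjusted p = 2.6e-13), and adjusted p = 0.0024 with an estimated correlation. The lignin and phenylpropanoid list shifted up in camera (adjusted p = 1.7e-05, and adjusted p = 0.016 with an estimated correlation). Of its 25 genes 5 were measured, of which 3 rose and 3 passed when adjusted over the list alone. The 3 were the peroxidase genes PRX52, PER71 and PER49, the last by 0.85 and 0.82 in myb36-1 and myb36-2, while HCT, a monolignol synthesis gene, was at 0.11 in the mean without passing. In myb36-2 alone the lignin list had adjusted p = 0.0042, and with an estimated correlation adjusted p = 0.072 as deposited and 0.022 on the common scale. Iron deficiency (7 genes), abscisic acid (5) and cortex genes (3) did not pass in the mean, with camera adjusted p of 0.58, 0.37 and 0.37 and 0 members called in each. In myb36-2 alone the cortex genes CO2 (0.63) and AT1G62510 (0.78) and the iron deficiency gene IMA2 (0.52) rose as deposited, and on the common scale AT1G62510 only. At least as many lists, 2 or more, passed under 22 of the 84 splits of the 9 arrays into 3 and 6, the real split included.

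Among lists with 1 or 2 measured members, the stress gene STZ (ZAT10), of the touch list, was 0.63 in myb36-1 without passing and rose by 2.01 in myb36-2. The flavonoid gene DFR was 0.45 without passing and rose by 0.82. RCA, encoding rubisco activase, was -0.18 in myb36-1 and fell by 0.50 in myb36-2, while the leaf gene LHCB4.1 was -0.24 and 0.01. The endodermal regulators JKD and BLJ were 0.09 and -0.02 in the mean, the suberin genes LTPG15 and FACT -0.25 and 0.17, the root hair genes EXPA7 and EXPA18 0.00 and 0.11, and PDF1.2 -0.08, none passing as deposited. On the common scale the mean of LTPG15 passed (-0.30), and FACT rose in myb36-2 as deposited (0.28) and not on the common scale. The heat shock gene HSP17.8 was -0.02 in myb36-1 and 0.35 in myb36-2, past the threshold as deposited and not on the common scale (0.12).

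In myb36-1 against Col-0, QQS, an orphan gene known for a role in starch metabolism, showed the largest rise among named genes, 3.02 ± 0.45 (adjusted p = 0.027 in limma), followed by PRX52, AT1G65500, AT5G52390 and AT1G49570. Its Col-0 arrays were spread at 3.48, 5.80 and 4.73, and its call was lost without Col-0 replicate 3 (adjusted p = 0.096) and without any single mutant array. AT2G40113, DIR9, AT1G71740, AT5G52790 and AT1G30750 showed the largest falls among named genes. Of 31325 probe sets, 155 were called, 71 higher and 84 lower, and 131 of the 155 were also called in myb36-2 with the same sign. On the common scale 148 were called, 72 higher and 76 lower. Leaving out any single Col-0 or myb36-1 array brought the count to between 74 and 92.

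In myb36-2 against Col-0, the largest rises among named genes were AT5G52390 (3.03), PRX52 (2.57), AT1G59865 (2.54 ± 0.15), AT1G49570 (2.50) and AT1G65500 (2.45). The largest falls among named genes were DIR24, AT1G71740, DIR9, AT2G40113 and AT1G30750. As deposited, 6669 probe sets were called, 6036 higher and 633 lower (90.5% higher). On the common scale 3149 were called, 1461 higher and 1688 lower (46.4% higher), and 2094 calls were shared with the same sign, so the direction of small changes in this line depends on the scale. The count was 4157 without Col-0 replicate 1, 3890 without Col-0 replicate 2 and 4350 without myb36-2 replicate 2.

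The mean of both mutants against Col-0 ranks genes by their average change. Among named genes called in both mutants, DIR24 (-3.75 ± 0.19), DIR9 (-3.45 ± 0.11) and AT1G71740 (-3.24 ± 0.17) stood lowest. PRX52 (2.71 ± 0.14), AT5G52390 (2.61 ± 0.19) and AT1G65500 (2.39 ± 0.16) stood highest among them. As deposited 1668 probe sets were called, 1371 higher and 297 lower, and on the common scale 1003, 473 higher and 530 lower. With both mutants pooled as 1 group 155 were called. The count was 521, 443 and 770 without Col-0 replicates 1, 2 and 3, and 996 and 859 without myb36-1 replicates 1 and 3.

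The mutants were also compared directly, with named genes only in the ranking. QQS was higher in myb36-1 than in myb36-2 by 3.42 ± 0.45 (adjusted p = 0.0034 in limma), DIR24 by 3.11 ± 0.22 (adjusted p = 2.9e-04) and AT1G71740 by 1.20 ± 0.19, followed by NVL (0.98), LCR39 (0.97) and AT1G62085 (0.94). Lower in myb36-1 were AT1G59865 (-1.86 ± 0.15), AT1G14480 (-1.71), AT5G41740 (-1.69), AT1G19650 (-1.62), PDC3, a pyruvate decarboxylase gene (-1.60), and the expansin-like gene EXLA3 (-1.50). SGN1 differed by 0.10 ± 0.13 and PRX52 by 0.28 ± 0.16, without passing. As deposited 4836 probe sets differed, 290 higher and 4546 lower in myb36-1, and on the common scale 1301, 685 higher and 616 lower; of the 131 shared calls 37 differed as deposited, and 19 of 130 on the common scale. In this contrast the Casparian strip list lay higher in myb36-1 relative to other genes, with camera adjusted p = 0.048 as deposited and 0.20 on the common scale. With an estimated correlation camera gave adjusted p = 0.28 and 0.42, and fry gave adjusted p = 0.23 and 0.0038. Its median difference as deposited was -0.08, against -0.17 over all tested probe sets. The count was 2810, 2584 and 2551 without myb36-1 replicates 1, 2 and 3, and 2855 and 2606 without myb36-2 replicates 2 and 3.

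Neighbours of MYB36 in gene order were examined because an insertion can affect nearby genes. Of the 10 measured genes on either side, 0 were called in myb36-1, where 155 of all 31325 tested probe sets were called. Their changes in myb36-1 ranged from -0.30 to 0.69. In myb36-2, 6 were called as deposited and 3 on the common scale, where 6669 and 3149 of all 31325 tested probe sets were called. Their median change as deposited was 0.12, against 0.16 over all tested probe sets. Whether neighbours were called more often than other genes was not tested. AT5G57510, chosen after its value was seen, was highest in both mutants. It was at 0.69 in myb36-1 without passing (adjusted p = 0.10 in limma) and at 1.28 in myb36-2. Its mean of both mutants, 0.99, passed (adjusted p = 0.0047 in limma). Genes called in both mutants were also counted along the chromosomes. The window from AT2G37840 to AT2G39445 on chromosome 2 held 5 of 100 genes, DIR9, the peroxidase gene AT2G38390, AT2G38600, AT2G38830 and YLS5, the last 4 named after their values were seen, against 0.419 expected (Bonferroni-adjusted binomial p = 0.012, 167 windows). No window passed with 50 genes per window (lowest adjusted p = 0.41) or 200 (0.14), and the adjusted p of this window was 0.11 on the common scale. The adjustment covers windows and not the several lists of calls that were scanned. For the myb36-1 calls the same window had a Bonferroni-adjusted binomial p of 0.023. The highest windows of the myb36-2 calls and of the calls in the mean (adjusted p = 0.39) did not pass.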

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

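The tests of scale and of shared direction below were chosen after the results were seen; the counts over other splits of the arrays were planned. The direct contrast of the mutants called 4836 probe sets as deposited, 4546 of them lower in myb36-1. On the common scale it called 1301, 685 higher and 616 lower, so most of the 4836 depend on the scale. Named genes that differed both as deposited and on the common scale, with myb36-1 minus myb36-2 on the log2 scale, were QQS (3.42), DIR24 (3.11), AT1G71740 (1.20), NVL (0.98), LCR39 (0.97), AT1G62085 (0.94), DIR9 (0.77), AT1G30750 (0.63), IMA2 (-0.68), AT5G19240 (-1.02), STZ (-1.38), EXLA3 (-1.50), PDC3 (-1.60), AT1G19650 (-1.62), AT5G41740 (-1.69), AT1G14480 (-1.71) and AT1G59865 (-1.86). Outside the tested probe sets, the 7083 left out had a median higher by 0.21 in myb36-2 than in Col-0.

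As deposited, rises far outnumbered falls in myb36-2. The shift depended on level, with a median log2 change of 0.29 in tested probe sets at mean levels of 3.05 to 3.52 and 0.07 in the brightest, from 8.66 to 13.8, unlike a single offset. The 7083 probe sets changed by 0.872 times the change of tested ones of the same level (0.18 against 0.21), as arrays on another scale would give. A wide rise of root transcripts may also account for it. By another measure, the array medians of the 7083 probe sets were higher by 0.21 on average in myb36-2 than in Col-0. That shift would argue against a wide rise if these probe sets were controls, which no source states. The scale and a wide rise therefore cannot be told apart here, since scale and line coincide. Processing of the myb36-2 arrays apart from the others would likewise coincide with line, and quantile normalisation may not remove all of its effect.

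More probe sets were called in myb36-2 than in myb36-1 on the common scale as well, 3149 against 148. Of probe sets called in myb36-2 and not in myb36-1, with separate Col-0 arrays for each mutant, 62.7%, 65.8% and 69.0% moved the same way in myb36-1, against 58.1% to 58.6% of all probe sets. Leaving out myb36-1 calls, of which 131 of 155 in the main fit shared the sign of a myb36-2 call, may lower these shares. The lowest share, 62.7% of 158, had an exact 95% binomial interval of 54.6% to 70.2%, which treats probe sets as independent. The intervals of 65.8% of 190 and 69.0% of 213 were 58.6% to 72.5% and 62.3% to 75.2%. Only these lay above the share over all probe sets for the same arrays (58.1% and 58.4%). These myb36-2 calls rest on a single Col-0 array, with its spread taken to be like that of the other lines. The same response at a larger size in myb36-2, and a difference of these arrays unrelated to MYB36, cannot be told apart by this test. The median change in myb36-1, counted as positive along the direction in myb36-2 so that opposite moves offset each other, was 0.0644 to 0.0937 times the median size in myb36-2. A small ratio is partly set by the choice of probe sets, since those called in myb36-1 were left out.

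For each pair of lines the 6 arrays make 10 splits, too few for a share under 0.05. The real split, 1 of 10 in each case, gave 155, 6669 and 4836 calls for myb36-1, myb36-2 and the direct contrast, and the highest other split gave 0 in each. For the mean of both mutants fitted as 2 groups, 2 of 84 splits gave as many calls as the real 155, a share under 0.05. The other was myb36-2 against the 6 remaining arrays with 7391, which points to a structure of the samples. On the common scale 2 of 84 gave as many calls, with 293 real and 2626 for that same split. Since the arrays of a line may be technical replicates, these shares do not exclude chance differences between lines. Of 100 splits into 3 groups of 3, drawn from a larger set, 1 gave as many shared calls, the real 131. The highest other split drawn gave 56. Splits that were not drawn may give more, since myb36-2 against the 6 remaining arrays gave 7391 calls in the fit of 2 groups. The real count was therefore the highest of those drawn only, which does not exclude chance. For the gene lists, 22 of 84 splits, the real one included, gave at least as many as the real 2, up to 3. Chance is therefore not excluded for that count.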

How the results depend on the processing

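The counts of calls in myb36-1 and in both mutants stayed within 1.5 times under both scalings, and the other 3 counts did not. The cause of these moves was not tested, except where fewer probe sets, arrays or a stricter threshold set it by construction. Quantile normalisation gave 3149 calls in myb36-2, 1003 in the mean and 1301 between mutants, and median centring 4082, 1024 and 1724. Without the dimmest 50% of probe sets these were 3136, 1087 and 2127. With only the arrays compared, myb36-1 had 94 calls and both mutants 85; the mean had 155 with both mutants pooled as 1 group over all 9 arrays. With 1 probe set per gene the counts were 98 for myb36-1, 4119 for myb36-2, 80 for both and 1111 for the mean. At an adjusted p of 0.01 they were 70, 2002, 57 and 289, and 1082 between mutants; with a log2 change of at least 1 they were 69, 637, 58 and 165, and 211 between mutants. Adjusting the larger of the p-values once gave 83 calls in both. With all deposited probe sets, an alternative chosen after seeing the data, myb36-1 had 81 calls, both 75 and the mean 855. Leaving out each array gave 74 to 126 in myb36-1, 3890 to 6409 in myb36-2, 69 to 112 in both, 443 to 1403 in the mean and 2551 to 4476 between mutants. The number of gene lists past the test was 2 under each alternative run. No window passed the exact binomial test after Bonferroni adjustment with 50 genes per window (lowest adjusted p = 0.412, on chromosome 1), with 200 (adjusted p = 0.142) or on the common scale (adjusted p = 0.111), both of these on chromosome 2 and the last chosen after seeing the data.

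The replicate numbers did not pair the arrays: residual correlations of the 9 same-numbered pairs lay between -0.19 and 0.08, and among all arrays of the other lines 1 of 9 arrays, Col-0 replicate 1, correlated best with its own number. With the number as a block the counts were 111 in myb36-1, 5784 in myb36-2, 102 in both, 1075 in the mean and 3955 between mutants. Of 209 results on named genes, each gene in both mutants and in the contrast it was chosen for, 4306 comparisons kept their side of the threshold, 142 lost the call and 35 gained it, with 0 reversed calls. Of 119 called results, 86 kept their call under each alternative run that held their probe set. The filters on dim probe sets left some results out, which were not counted as lost. When an array was left out 14 lost it: QQS, AT4G12490, AT5G09290, AT5G19240 and AT5G36925 in myb36-1, FACT, HSP17.8, LCR39, PER72 and RCA in myb36-2, LOTR1, PER39 and DFR in the mean, and AT1G62085 between mutants. Of the 24 shared genes named by rule, 20 to 23 stayed called in both mutants when an array was left out, and of the 131 shared calls as few as 65 did. No signal above background is given per probe set, so values near the lower end, such as those of DIR9 and DIR24 in myb36-2, may understate a fall.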

Other observations

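Class III peroxidases, the enzyme family that oxidises phenolics in the cell wall, were listed after several had been seen among the shared calls. Of 64 measured, 8 were called in both mutants against 0.267 expected. PRX52, AT1G49570, PER71, Prx37 (0.91 in myb36-1 and 0.87 in myb36-2) and PER49 rose, and PER9, AT2G38390 (-0.83 and -0.94) and AT3G32980 (-0.51 and -0.44) fell. On the common scale 7 were called in both, 5 higher and 2 lower, without AT3G32980. The odds ratio was 38.4 (15.2 to 85.5), with Fisher's exact p = 2.2e-10, two-sided; since the family was chosen from these calls, that p describes the data and tests nothing new. Members were called in both directions, and whether the family shifted in a single direction on average stays open: camera, against other genes, gave p = 0.836 with an estimated correlation, while fry, against no change, gave p = 0.0026 as deposited and p = 0.067 on the common scale.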
